A study of Mus musculus with 12 samples.

How the data were processed

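Messenger RNA was measured in 12 mouse libraries of bone-marrow derived macrophages. Per the labels, dTomato+ macrophages were sorted from ex vivo assays that used dissociated brain tumor. The series title concerns the recycling of myelin by macrophages in brain cancer. Small numbers of sorted cells were lysed, total RNA was purified on columns with a DNase step, and cDNA was made with an oligo-dT primer and template switching, per the labels' protocols. The 4 groups of 3 libraries are named Control, Myelin Alone, Tumor without Myelin and Full Tumor. Each group holds 1 library of each of the mn numbers 957, 958 and 016. The labels do not say what "mn" stands for, how long the macrophages were exposed, what the Control macrophages were given, or which tumor model gave the material of these libraries. Nothing says that the 3 libraries of a group come from separate animals, so p-values measure only the spread between these samples, which may be technical.

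The authors deposited a table of raw counts per gene, whole numbers with no normalization, with the Ensembl identifier, symbol, biotype and position of each gene. Coordinates are on mm10, the build named in the submitters' processing notes. The aligner, the counting program and the strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart. The table holds 24728 genes, each with at least 1 count over the libraries, 12 symbols that occur more than once, and 0 entries without a gene. All 12 value columns matched a sample by the label. Totals were 17071673 to 21689624 counts per library, a ratio of 1.27, and 16465 to 17861 genes were detected per library. A count of 0 allows up to 3 counts, which is 0.138 to 0.176 CPM depending on the library. Such floors cover counting error only, since the counts carry no molecular identifiers.

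CPM (with the library total multiplied by the TMM factor), log2 fold changes and all tests were computed here from the deposited counts. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, glmQLFit and glmQLFTest) with TMM factors (0.965 to 1.06) and filterByExpr, on all 12 libraries in a single fit with group as the only term. It kept 13414 genes, which held 99.9% of the counts; 11608 of them were among the 14944 protein-coding genes of the table. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. Means are given with the SD over the 3 libraries of a group. Log2 fold changes are given with an approximate standard error. It was derived from the test, as the absolute log2 fold change over the square root of the F statistic. The comparisons were 5 between groups and 1 interaction, the effect of myelin with tumor material (Full Tumor minus Tumor without Myelin) minus its effect without (Myelin Alone minus Control). No replicate pair was a duplicate: chi-square per degree of freedom over genes with at least 20 counts was 23.9 to 143 within groups.

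The mn number is shared by groups, so whether it pairs the libraries was checked before the calls of the fits were compared. Deviations from the group means correlated at r above 0.1 in 18 of 18 same-numbered pairs (across genes, 0.120 to 0.631, median 0.329), against a median of −0.200 for pairs of different numbers. Deviations cancel within a group, so positive values for same-numbered pairs push the others negative. The median of −0.200 is thus no separate evidence. Of the 12 libraries, 11 correlated best with a library of their own number. The numbers therefore pair the libraries, and values "with the block" come from the same fit with the mn number added. The biological coefficient of variation was 0.414 with 8 residual degrees of freedom and 0.266 with the block and 6.

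The procedure was tested on simulated data for Full Tumor against Control, with 200 of 13414 genes changed in each of 3 simulations. The 24 tested members of the cholesterol synthesis list were lowered besides these 200, and calls among them were not counted as false. With group only, 11.0% of 2-fold and 45.0% of 4-fold changes were recovered, with a mean of 0 false calls. With the block these shares were 47.3% and 67.7%, with a mean of 6.33 false calls.

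Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in the same direction, were run beside it. There were 32 lists, of lipid handling, macrophage states, stress, other cell types and housekeeping transcripts. The list of erythroid markers had 0 of 8 members among the tested genes and could not be tested.

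Genes were named by a rule with 3 parts. The first part takes genes with an adjusted p under 0.05, at least 10 CPM in the higher group and the same direction in the 3 same-numbered pairs, with the 8 highest and the 8 lowest log2 fold changes (5 each way for the interaction). Predicted and clone names were left out of it. The next part takes up to 4 members of each list with the smallest p, and the last always takes a fixed set that holds Abca1, Abcg1, Apoe, Gpnmb, Trem2, Spp1, Fabp5, Plin2, Arg1, Il1b and Mki67. The first part gave no gene in the fit without the block and was then applied to the calls with the block, a step chosen after seeing the data. The rule takes 799 genes over the 6 comparisons, counted in each comparison. Of these, 103 are named, among them all from the first part except for genes that are not reported here, and which others to name was decided after their values were seen.

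The groups, comparisons, tests, lists, naming rule and the following alternatives were fixed before the data were examined. These were RLE size factors, library totals alone, no low-count filter, at least 5 CPM in 3 libraries, DESeq2 (1.42.0), limma-voom, the block and thinning to the smallest total. They also held fitting only the groups compared, counting only the calls with a change of at least 2-fold, and leaving out each library or each mn number. Added after seeing the data were these alternatives with the block as the base, pooled myelin and tumor effects, and the tumor effect by mn number. Agreement between comparisons used the 8256 genes with a mean of at least 10 CPM and 20 simulated sets of unchanged groups, which kept the differences between mn numbers and went through the fits with and without the block. Other samples of the study were not analysed here.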

Results

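The transcriptome of sorted mouse bone-marrow derived macrophages was measured after ex vivo assays with myelin, with tumor material freed of myelin or with the full tumor, beside a group named Control, for which the labels do not say what the cells were given. Myelin is the lipid-rich sheath that oligodendrocytes wrap around axons. The groups were Control, Myelin Alone, Tumor without Myelin and Full Tumor, with 3 libraries each. Every group held 1 library of each mn number, 957, 958 and 016. In that order of numbers, libraries totalled 18360267, 17133919 and 20725607 counts in Control, and 19185453, 17571197 and 18269374 in Myelin Alone. They totalled 19469186, 17333519 and 17071673 in Tumor without Myelin, and 19171573, 17827098 and 21689624 in Full Tumor. Mitochondrially encoded transcripts took 0.287% to 0.941% of the counts.

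The mn number set the libraries apart more than the group did. It accounted for 39.8% of the variance over genes, where its degrees of freedom alone would give 18.2%, and the group for 22.7%, where they would give 27.3%. The last value supposes that the number has no effect. The large share of the number leaves less for the group, so 22.7% does not speak against an effect of the group. The 4 libraries of number 016 stood apart on the first principal component, and within each number the tumor libraries lay below Control and Myelin Alone on PC2.

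**Figure D1:**
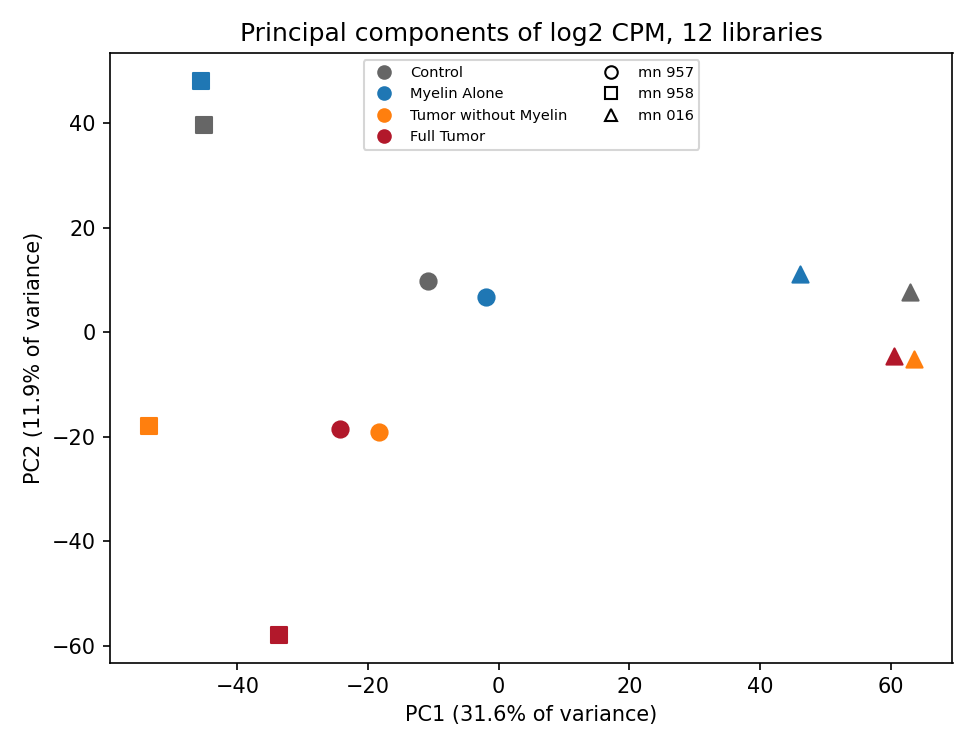
Principal components of log2 CPM for the 12 libraries, with PC1 (31.6% of variance) on the x axis and PC2 (11.9%) on the y axis. Each point is a library, its color the group and its shape the mn number. Libraries of number 016 lie at PC1 values of 46.1 to 63.6, and the other libraries at −53.6 to −1.87.

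Myelin Alone was compared with Control to ask what myelin by itself did to the macrophages. Transcripts of cholesterol synthesis fell. The list of synthesis enzymes and other targets of SREBP2, the transcription factor that raises sterol supply, had a median log2 fold change of −0.69 and was lower in 24 of 24 measured members (camera adjusted p = 1.5e-38, and 0.000111 with an estimated correlation). Sqle, squalene epoxidase (ENSMUSG00000022351, chromosome 15, 59315077 to 59331192), fell from 158 ± 58.2 CPM in Control to 65.7 ± 10.7 with myelin (SD, n = 3), a log2 fold change of −1.23 ± 0.14 with the mn number as a block (edgeR adjusted p = 0.0137). Cyp51, lanosterol demethylase (ENSMUSG00000001467, chromosome 5, 4081145 to 4104746), fell from 98.2 ± 17.7 to 47.1 ± 6.99 CPM, by 1.06 ± 0.14 on the log2 scale with the block (edgeR adjusted p = 0.0307).

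Fdft1, squalene synthase, was measured at 53.8 ± 2.58 CPM in Control and 27.1 ± 4.68 CPM with myelin (SD, n = 3). Its log2 fold change of −0.98 ± 0.22 with the block did not pass (edgeR adjusted p = 0.273). Among the 24 measured members of the list, edgeR called 0 over all genes and 16 adjusted over the list alone with group only, against 2 and 17 with the block, all of them lower. Medians of the list by number 957, 958 and 016 were −0.55, −0.86 and −0.79.

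Targets of LXR, the nuclear receptor that senses oxysterols, moved the other way. The list of LXR targets and cholesterol efflux genes rose, with a median of 0.31 and 14 of 17 members higher (camera adjusted p = 7.0e-05). With an estimated correlation the adjusted p was 0.270 with group only and 0.0325 with the block. Pltp, the phospholipid transfer protein (ENSMUSG00000017754, chromosome 2, 164839518 to 164857711), rose from 169 ± 87.2 to 379 ± 197 CPM (SD, n = 3), by 1.15 ± 0.13 on the log2 scale with the block (edgeR adjusted p = 0.0137). The cholesterol exporters Abcg1 (0.76 ± 0.11, edgeR adjusted p = 0.0512) and Abca1 (2.12 ± 0.41, edgeR adjusted p = 0.190) did not pass with the block. Neither did Smpdl3a, a sphingomyelinase-like phosphodiesterase (0.31, edgeR adjusted p = 0.393). With group only, edgeR called 0 members over all genes and 0 adjusted over the list alone, against 1 and 8 with the block, all higher. Medians by number were 0.19, 0.47 and 0.28.

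Small upward shifts were also called for the lists of hypoxia and glycolysis (median 0.16), lysosome (0.11), NRF2 and oxidative stress (0.12), scavenger and phagocytic receptors (0.09) and microglia markers (0.15), at camera adjusted p values of 0.0014 to 0.021. Lists of interferon response (−0.68), proliferation (−0.31) and neutrophil markers (−1.0) fell, at camera adjusted p values of 2.1e-07 to 0.024. By number 957, 958 and 016 interferon medians were −0.38, −0.31 and −0.85, and neutrophil medians −0.99, −2.35 and −0.57, while the lysosome medians were 0.27, 0.14 and −0.02, with no rise in 016. Of these 8 lists, 0 kept the call with an estimated correlation, where adjusted p was 0.224 to 0.800. EdgeR called 0 of their members over all genes with group only or with the block. Adjusted over the list alone it called 0 with group only, and with the block 4 scavenger receptors, 2 lysosome, 2 microglia and 1 neutrophil member. With the block the lists of lipid-associated macrophage markers (camera adjusted p = 0.031, from 0.10) and of stress genes (0.0032, from 0.10) passed too, the first higher and the other lower, with 0.543 and 0.431 with an estimated correlation, though the stress median in 958 was 0.04.

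Ccl6, a macrophage chemokine, and Dok2, an adaptor that restrains tyrosine kinase signaling, were the other genes that fell with the block, by 0.81 ± 0.11 and 0.76 ± 0.10 on the log2 scale (edgeR adjusted p = 0.0353 and 0.0307). Markers of lipid-laden macrophages were not called with the block. Their log2 fold changes were 0.38 for Fabp5, 0.12 for Gpnmb, −0.04 for Trem2, 0.20 for Spp1 and 0.36 for Apoe (edgeR adjusted p of 0.690 to 1). The lipid droplet coat gene Plin2 stood at 0.30 ± 0.07, the lysosomal membrane gene Scarb2 at 0.57 and the receptor gene Axl at 0.49 (edgeR adjusted p = 0.322, 0.273 and 0.616).

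With group only, edgeR's quasi-likelihood test called 0 genes between Myelin Alone and Control, with 279 at an unadjusted p under 0.05, and DESeq2 called 7 and limma-voom 0. EdgeR adjusted p of the named genes was 0.770 to 1 with group only. The block gave 1 higher and 4 lower (810 unadjusted), or 2 and 4 when scaled by library totals alone. Without Control, Full Tumor, Tumor without Myelin or Myelin Alone 957 the 5 calls became 1, 3, 2 and 0, without Control, Tumor without Myelin or Myelin Alone 958 they became 0, 2 and 0, and without Tumor without Myelin or Myelin Alone 016, 2 and 0. There were 0 calls without number 957 or 958, and 9 without 016, of which 0 were among the 5. Without Control 016 there were 7, of which 3 were.

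Full Tumor was compared with Control to ask what the whole dissociated tumor, myelin included, did to the macrophages. Cholesterol synthesis fell here too and cholesterol efflux rose. Sqle fell from 158 ± 58.2 CPM in Control to 56.2 ± 12.2 (SD, n = 3), by 1.47 ± 0.14 on the log2 scale with the block (edgeR adjusted p = 0.000644). Pltp rose by 1.68 ± 0.13 and Abcg1 (ENSMUSG00000024030, chromosome 17, 31057675 to 31117988) by 0.86 ± 0.11, from 563 ± 134 to 1029 ± 230 CPM (edgeR adjusted p = 0.000297 and 0.00474). Abca1 (ENSMUSG00000015243, chromosome 4, 53030787 to 53159895) rose from 26.4 ± 19.8 to 181 ± 47.6 CPM, by 3.07 ± 0.43 (edgeR adjusted p = 0.0071).

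Cyp51 and Fdft1 fell by 1.07 ± 0.14 and 1.28 ± 0.22 with the block (edgeR adjusted p = 0.00474 and 0.0224). The synthesis list had a median of −0.59 and 22 of 24 members lower (camera adjusted p = 3.9e-26, and 0.000458 with an estimated correlation). EdgeR called 0 of its members over all genes and 9 adjusted over the list alone, against 5 and 16 with the block. The LXR list had a median of 0.36 and 15 of 17 members higher (camera adjusted p = 2.1e-07). Its adjusted p with an estimated correlation was 0.0714 with group only and 0.00825 with the block. EdgeR called 0 of its members over all genes and 2 adjusted over the list alone, against 4 and 10 with the block. By number 957, 958 and 016 the synthesis medians were −0.56, −0.39 and −0.77, and the LXR medians 0.37, 0.43 and 0.38.

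**Figure D2:**
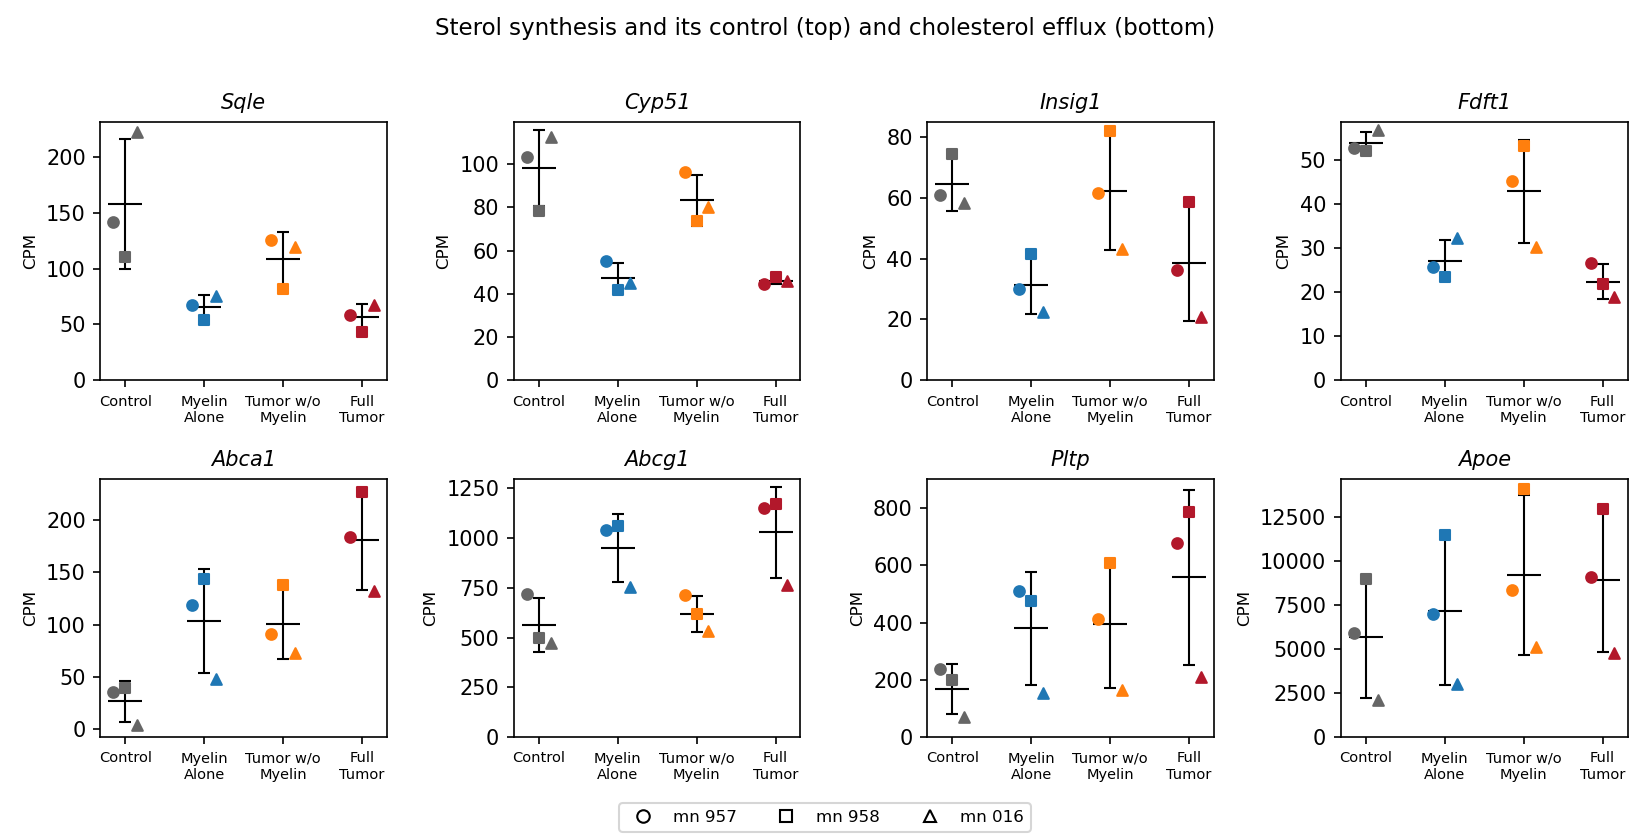
CPM of genes of sterol synthesis and its control (Sqle, Cyp51, Insig1, Fdft1) and of cholesterol efflux genes (Abca1, Abcg1, Pltp, Apoe) in the 4 groups on the x axis. Points are libraries, with the mn number as the shape, and bars are the mean ± SD of 3 libraries. Mean CPM of Sqle is 158 in Control, 65.7 in Myelin Alone, 109 in Tumor without Myelin and 56.2 in Full Tumor.

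Receptors for debris, lipids and immune complexes rose with Full Tumor. The list of scavenger and phagocytic receptors had a median of 0.49 and 20 of 22 members higher (camera adjusted p = 6.4e-10, and 0.0153 with an estimated correlation). With the block, Fcgr1, the high-affinity IgG receptor (ENSMUSG00000015947, chromosome 3, 96282909 to 96293969), rose from 63.1 ± 29.2 to 194 ± 75.2 CPM (SD, n = 3), by 1.64 ± 0.22 on the log2 scale. Tgm2, transglutaminase 2 (ENSMUSG00000037820, chromosome 2, 158116402 to 158146436), an enzyme of the alternative activation list and not of the receptor list, rose by 1.30 ± 0.11. Axl, a receptor for apoptotic cells, rose by 0.80 ± 0.15, and its ligand Gas6 by 0.97 ± 0.17 (edgeR adjusted p of 0.000356 to 0.0373 for these 4 genes). EdgeR called 0 receptors over all genes and 4 adjusted over the list alone, against 7 and 11 with the block, all higher. Medians by number 957, 958 and 016 were 0.54, 0.29 and 0.53. In the same libraries microglia markers summed to 1265 ± 152 CPM, against 938 ± 82.5 in Control (SD, n = 3).

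Genes known from microglia and tissue macrophages rose beside them. Fcrls, a marker that separates microglia from other macrophages (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738), rose from 14.8 ± 6.40 to 83.9 ± 26.8 CPM (SD, n = 3), by 2.49 ± 0.35 with the block (edgeR adjusted p = 0.00739). The list of microglia markers had a median of 0.82, with 9 of 11 members higher and 6 of the 11 at 10 CPM or more in Control. Its camera adjusted p was 1.8e-07. With an estimated correlation adjusted p was 0.0714 with group only and 0.0262 with the block, and medians by number 957, 958 and 016 were 0.47, 0.84 and 1.01. The macrophage identity list (median 0.15, 16 of 21 higher, camera adjusted p = 7.9e-05) had 0.269 with an estimated correlation, and 0.0137 with the block. In it C1qa, of the complement complex, rose by 1.13 ± 0.20 with the block (edgeR adjusted p = 0.0252). Adjusted over the list alone edgeR called 2 microglia and 1 identity member and 0 over all genes, against 5 and 8, with 2 and 6 over all genes, with the block.

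The highest and lowest fold changes with the block included genes outside these groups. Il18bp, which encodes a secreted interleukin inhibitor (ENSMUSG00000070427, chromosome 7, 102014885 to 102018690), rose from 6.97 ± 0.188 to 109 ± 81.1 CPM (SD, n = 3), by 3.53 ± 0.42. The membrane proteins Ms4a4a (3.00 ± 0.41) and Ms4a6b (2.29 ± 0.17, ENSMUSG00000024677, chromosome 19, 11516512 to 11531256) rose, as did the matrix protease Mmp14 (2.25 ± 0.37) and the lipid-binding receptor Cd300lf (2.20 ± 0.25). The chemokine gene Ccl2 stood at 1.28, 2.31 and 194 CPM in Control 957, 958 and 016 and at 8.98, 21.0 and 352 in Full Tumor (2.21 ± 0.43, against 0.95 ± 2.24 with group only). Nqo1, a quinone reductase driven by NRF2, fell by 1.23 ± 0.23, Serpinb9b, a serine protease inhibitor (ENSMUSG00000021403, chromosome 13, 33027416 to 33041884), by 1.18 ± 0.18, coagulation factor F10 by 1.87 ± 0.27 and Olfm1 by 1.17 ± 0.22. Mpo, myeloperoxidase of neutrophil granules, fell by 5.19 ± 0.62, but its reads came nearly all from number 016, at 0.107, 1.10 and 111 CPM in Control and 0, 0 and 3.88 in Full Tumor. EdgeR's adjusted p was 0.000297 to 0.0404 for these genes.

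Interferon-induced transcripts rose as a list, with a median of 1.49 and 28 of 30 members higher (camera adjusted p = 6.0e-19, and 0.20 with an estimated correlation). By number 957, 958 and 016 the medians were 2.15, 2.33 and −0.74, so the rise did not hold in number 016. No member passed with the block over all genes. The interferon regulator Irf7 stood at 2.17 ± 0.89 (edgeR adjusted p = 0.432). Adjusted over the list alone edgeR called 0 members with group only and 4 with the block.

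Lists of alternative activation (median 0.53, camera adjusted p = 7.2e-05), lysosome (0.18, 0.00012), inflammatory cytokines (0.36, 0.028), class II presentation (0.68, 0.044), monocyte markers (0.44, 0.028) and oligodendrocyte transcripts (0.08, 0.017) also rose, and ribosomal proteins (−0.09, 0.044) fell. With an estimated correlation adjusted p was 0.0264 for alternative activation and 0.105 to 0.774 for the other 6. By number 957, 958 and 016 alternative activation had medians of 0.81, 0.04 and 0.55. Several rises did not hold in 016: medians were 0.15, 0.39 and −0.07 for lysosome, 0.42, 0.56 and −0.03 for inflammatory cytokines, 0.69, 0.64 and −0.25 for class II presentation and 0.99, 1.72 and −0.35 for monocyte markers. EdgeR called 0 of their members over all genes, and adjusted over the list alone 2 oligodendrocyte, 1 lysosome and 1 alternative activation member. With the block it called 4, 1 and 1 over all genes and 10, 1 and 2 adjusted over the list alone, for lysosome, alternative activation and inflammatory cytokines. With the block the oligodendrocyte list no longer passed (camera adjusted p = 0.051). Hypoxia (0.032) and mitochondrially encoded transcripts (0.016) were then called higher, and NRF2 (0.049), proliferation (0.0070) and neutrophil markers (0.017) lower, at 0.235 to 0.633 with an estimated correlation. All but NRF2 changed sign between numbers, with medians of −0.01, 0.09 and 0.37 for hypoxia, 0.14, −0.28 and 1.03 for mitochondrial transcripts, −0.37, −0.75 and 0.42 for proliferation and 0.37, −0.17 and −2.87 for neutrophil markers.

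Apoe, the apolipoprotein that carries cholesterol out of macrophages, Plin2 and Scarb2 rose with the block, by 0.77 ± 0.13, 0.47 ± 0.07 and 0.77 ± 0.13 (edgeR adjusted p = 0.0174, 0.00976 and 0.0174). Gpnmb (0.19), Trem2 (−0.11), Spp1 (0.44), Arg1 (1.53 ± 1.76), Il1b (2.72 ± 1.24) and Mki67 (−0.41 ± 0.33) did not pass (edgeR adjusted p of 0.0568 to 0.857).

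With group only, edgeR called 0 genes between Full Tumor and Control, with 560 at an unadjusted p under 0.05 and adjusted p of 0.124 to 1.00 for the named genes, while DESeq2 called 43 and limma-voom 0. Without a low-count filter there were 3, and without number 016 there were 69. The block gave 85 higher and 24 lower (1319 unadjusted), or 67 and 34 when scaled by library totals alone. In place of its 109 calls there were 37, 33, 48, 29 and 61 without Control 957, Control 958 or Full Tumor 957, 958 or 016, and 1, 4 and 183 without number 957, 958 or 016. The 183 held 71 of the 109, and 107 calls without Control 016 held 68. Of the 26 named calls with the block, between 1 and 12 were lost without any 1 library. Losses were largest without Control 958 or Full Tumor 958 (12), Control 957 (11), Full Tumor 957 (9) and Full Tumor 016 (8). All kept their direction, which the naming rule favors.

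Tumor without Myelin was compared with Control to ask what tumor material did once myelin had been removed. Ms4a6b rose from 24.8 ± 12.5 to 139 ± 68.9 CPM (SD, n = 3), by 2.48 ± 0.17 on the log2 scale with the block. Fcrls rose from 14.8 ± 6.40 to 109 ± 34.8 CPM, by 2.87 ± 0.35, and Siglec1, a sialic acid receptor of macrophages, from 7.20 ± 3.03 to 31.0 ± 15.8, by 2.13 ± 0.26 (edgeR adjusted p of 0.00013 to 0.00554 for these 3 genes). The cholesterol synthesis list had a median of −0.09 with 18 of 24 members lower (camera adjusted p = 0.039, and 0.224 with an estimated correlation), but by number 957, 958 and 016 medians were −0.00, 0.00 and −0.31, so the fall lay in 016. Sqle, at −0.51 ± 0.13 with the block, did not pass (edgeR adjusted p = 0.151).

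More microglia-associated genes rose, namely Tmem119 (2.64 ± 0.48), the purinergic receptor P2ry13 (3.30 ± 0.59) and Aif1, a calcium-binding protein of macrophages and microglia (1.75 ± 0.18). C1qa (1.36 ± 0.20) rose as well (edgeR adjusted p of 0.00209 to 0.0297 with the block for these 4 genes). The list of microglia markers had a median of 0.68 and 9 of 11 members higher (camera adjusted p = 2.3e-10, and 0.0441 with an estimated correlation), and by number 957, 958 and 016 medians were 0.61, 0.37 and 1.83. EdgeR called 0 of its members over all genes and 3 adjusted over the list alone, against 4 and 5 with the block. The macrophage identity list rose, with 21 of 21 members higher (median 0.29, camera adjusted p = 3.3e-07), at 0.186 with an estimated correlation and 0.0149 with the block. For it edgeR called 0 over all genes and 1 adjusted over the list alone, against 5 and 9 with the block.

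Scavenger and phagocytic receptors rose, with a median of 0.35 and 18 of 22 members higher (camera adjusted p = 2.9e-07, and 0.0441 with an estimated correlation). Fcgr1 rose by 1.74 ± 0.22 with the block, Axl by 0.87 ± 0.15 and the integrin subunit Itgav by 0.73 ± 0.15. Tgm2, not of the receptor list, rose by 1.13 ± 0.11 with the block (edgeR adjusted p of 0.00159 to 0.049 for all of these genes). EdgeR called 0 receptors over all genes and 4 adjusted over the list alone, against 5 and 10 with the block. Medians by number 957, 958 and 016 were 0.26, 0.25 and 0.58, and microglia markers summed to 1357 ± 229 CPM in the same libraries, against 938 ± 82.5 in Control (SD, n = 3). The LXR list rose as well, with a median of 0.19 (camera adjusted p = 0.00098), at 0.211 with an estimated correlation and 0.0354 with the block. Its medians by number were −0.00, 0.31 and 0.26. Pltp, Apoe and Abca1 rose by 1.21 ± 0.13, 0.81 ± 0.13 and 2.21 ± 0.42 with the block (edgeR adjusted p = 0.00289, 0.0149 and 0.0347), and Abcg1, at 0.15 ± 0.11, did not pass (edgeR adjusted p = 0.763). EdgeR called 0 members of that list over all genes and 0 adjusted over the list alone, against 3 and 5 with the block.

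Genes of the NRF2 response to oxidants fell, with a median of −0.19 and 16 of 21 members lower (camera adjusted p = 2.8e-05, and 0.0317 with an estimated correlation). Nqo1 fell from 32.0 ± 19.8 to 12.99 ± 7.77 CPM (SD, n = 3), by 1.33 ± 0.23 on the log2 scale with the block (edgeR adjusted p = 0.0244). Srxn1 (−0.52 ± 0.12) and catalase, Cat (−0.47 ± 0.14), did not pass (edgeR adjusted p = 0.076 and 0.217). EdgeR called 0 members over all genes and 0 adjusted over the list alone, against 1 and 4 with the block. Medians by number 957, 958 and 016 were −0.29, −0.18 and −0.21.

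Among the largest changes with the block, Il18bp (2.78 ± 0.41), Ms4a4a (2.73 ± 0.41) and Mmp14 (2.00 ± 0.37) rose. Serpinb9b fell by 1.67 ± 0.19, Dio2, an enzyme that activates thyroid hormone, by 1.72 ± 0.26, the glutathione transferase Mgst2 by 1.48 ± 0.26, F10 by 1.34 ± 0.27 and Gramd4 by 1.22 ± 0.23. Lat, an adaptor of T cell receptor signaling, fell by 1.44 ± 0.27 and Mpo by 3.80 ± 0.56. EdgeR's adjusted p was 0.00296 to 0.0495 for these 10 genes. Reads of Mpo and Lat lay mostly in number 016, where Control and Tumor without Myelin held 111 and 10.6 CPM of Mpo and 47.0 and 16.9 CPM of Lat.

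**Figure D3:**
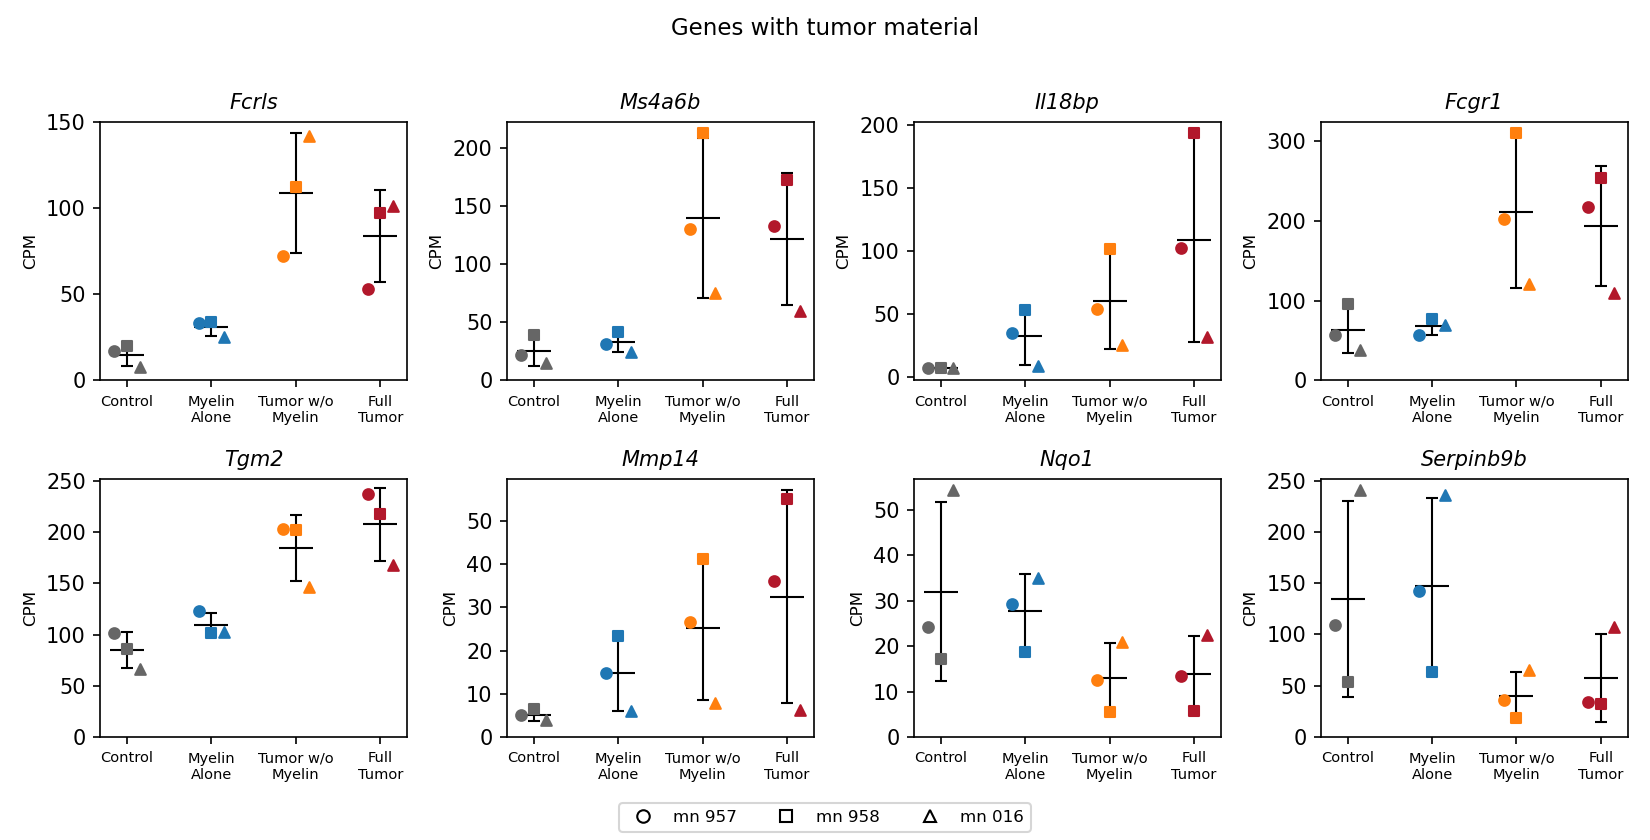
CPM of 8 genes that differed with tumor material, in the 4 groups on the x axis. Points are libraries, with the mn number as the shape, and bars are the mean ± SD of 3 libraries. Mean CPM of Fcrls is 14.8 in Control, 30.7 in Myelin Alone, 109 in Tumor without Myelin and 83.9 in Full Tumor.

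The interferon list rose, with a median of 1.75 and 29 of 30 members higher (camera adjusted p = 5.6e-30, and 0.104 with an estimated correlation), though not in number 016 (medians 2.15, 2.68 and −0.15). Ifit2, an interferon-induced RNA-binding protein, stood at 2.24 ± 0.74 with the block and did not pass (edgeR adjusted p = 0.291). EdgeR called 0 members over all genes, and 19 adjusted over the list alone with group only against 12 with the block. Lists of alternative activation (0.35, camera adjusted p = 0.00098), inflammatory cytokines (0.35, 0.020), class II presentation (0.54, 0.018) and astrocyte markers (0.42, 0.020) rose. Those of ribosomal proteins (−0.16, 0.00052), neutrophil markers (−0.72, 0.0498) and ER stress (−0.03, 0.0498) fell. With an estimated correlation adjusted p was 0.0441 for alternative activation and 0.186 to 0.665 for the other 6, and with the block ER stress no longer passed (camera adjusted p = 0.065). Medians by number 957, 958 and 016 were 0.49, 0.51 and −0.04 for inflammatory cytokines, 0.68, 0.69 and 0.11 for class II presentation, 0.00, 1.76 and 0.65 for astrocyte, −0.99, 0 and −1.63 for neutrophil markers and −0.28, 0.02 and 0.16 for ER stress, so these did not move alike in each number. EdgeR called 0 members of these 7 lists over all genes and, adjusted over the list alone, 1 of alternative activation.

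With group only, edgeR called 0 genes between Tumor without Myelin and Control, with 548 at an unadjusted p under 0.05 and adjusted p of 0.123 to 1.00 for the named genes, while DESeq2 called 54 and limma-voom 0. Without a low-count filter there was 1, and without number 016 there were 61. The block gave 75 higher and 25 lower (1272 unadjusted). In place of its 100 calls there were 18, 38, 31, 29 and 13 without Control 957, Control 958 or Tumor without Myelin 957, 958 or 016, and 6, 4 and 153 without number 957, 958 or 016. The 153 held only 45 of the 100, and 95 calls without Control 016 held 49. Of the 25 named calls with the block, between 2 and 17 were lost without any 1 library. Losses were largest without Tumor without Myelin 016 (17), Control 957 (16) and Tumor without Myelin 958 (14). All kept their direction, which the naming rule favors.

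Full Tumor was compared with Tumor without Myelin to ask what myelin added when the rest of the tumor material was present. Cholesterol synthesis fell again, with a median of −0.49 and 23 of 24 members lower (camera adjusted p = 9.7e-26, and 0.000456 with an estimated correlation). By number 957, 958 and 016 medians were −0.68, −0.47 and −0.46. No single gene passed with the block. Cyp51, at 83.3 ± 11.7 CPM without and 46.1 ± 1.42 CPM with myelin (SD, n = 3), stood at −0.84 ± 0.14 (edgeR adjusted p = 0.174). Abcg1, at 620 ± 90.6 and 1029 ± 230 CPM, stood at 0.72 ± 0.11 (edgeR adjusted p = 0.132).

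Fdft1 (−0.94 ± 0.22), Abca1 (0.86 ± 0.39), Plin2 (0.28 ± 0.07), heme oxygenase Hmox1 (0.43 ± 0.19) and Fcrls (−0.39 ± 0.32) were not called either (edgeR adjusted p of 0.989 to 1 with the block). Lists of NRF2 (median 0.11, camera adjusted p = 0.0021), hypoxia (0.16, 0.0060), lysosome (0.07, 0.013), LXR (0.13, 0.039) and lipid-associated macrophage markers (0.07, 0.045) rose. Those of interferon response (−0.28, 0.0084), astrocyte (−0.32, 0.0089) and dendritic cell markers (−0.29, 0.039) fell. Medians by number 957, 958 and 016 changed sign for lipid-associated (0.10, 0.10 and −0.02) and dendritic cell markers (0.11, −0.44 and −0.63). With an estimated correlation adjusted p was 0.0474 for NRF2, which became 0.0537 with the block, and 0.203 to 0.638 for the other 7. With the block the list of PPAR targets (camera adjusted p = 0.034, median 0.03, mean −0.11) and proliferation (lower, 0.00026) passed, at 0.478 and 0.581 with an estimated correlation.

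With group only, edgeR called 0 genes between Full Tumor and Tumor without Myelin, with 161 at an unadjusted p under 0.05, while DESeq2 called 5 and limma-voom 0. The block also gave 0 (520 unadjusted), with DESeq2 at 13 and limma-voom at 0, and 1 without Control 016 or Full Tumor 016. Adjusted over the list alone, edgeR called 5 synthesis genes with group only and 11 with the block, all lower, and of LXR targets 0 and 2.

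The effects of myelin without and with tumor material use no library in common. Across 8256 genes their log2 fold changes correlated at r = 0.303, against a mean of 0.000715 and a range of −0.0225 to 0.0327 in 20 simulated sets of unchanged groups. The block gave 0.283 (simulated 0.00273, −0.0209 to 0.0347). Genes are not independent replicates, and r was 0.176, 0.133 and 0.204 without number 957, 958 or 016.

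Full Tumor was compared with Myelin Alone to ask what the rest of the tumor material added to myelin. Ms4a6b rose from 32.4 ± 8.48 to 121 ± 57.1 CPM (SD, n = 3), by 1.81 ± 0.17 on the log2 scale with the block, and Ctsc, cathepsin C, from 168 ± 44.9 to 368 ± 113 CPM, by 1.14 ± 0.15. Fcgr1 (1.41 ± 0.22) and Tgm2 (0.91 ± 0.11) rose, and Serpinb9b fell by 1.38 ± 0.19 (edgeR adjusted p of 0.00316 to 0.0435 for these 5 genes). Genes of sterol synthesis and efflux were not called, with Abcg1 at 0.10 ± 0.11 with the block (edgeR adjusted p = 0.912) and a synthesis median of 0.06 (camera adjusted p = 0.79).

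Ms4a4a (3.28 ± 0.42), the immediate early nuclear receptor Nr4a1 (2.48 ± 0.38), Siglec1 (1.82 ± 0.26), Nxpe5 (1.48 ± 0.22) and Aif1 (1.27 ± 0.18) also rose with the block (edgeR adjusted p of 0.0167 to 0.0344). Fcrls, at 1.42 ± 0.33, did not pass (edgeR adjusted p = 0.179). The scavenger receptor list rose (median 0.32, 16 of 22 higher, camera adjusted p = 0.00014), at 0.0801 with an estimated correlation and 0.0284 with the block. The macrophage identity list did too (0.30, 19 of 21 higher, 2.5e-06), at 0.211 with an estimated correlation and 0.0186 with the block. NRF2 genes fell (−0.21, 18 of 21 lower, camera adjusted p = 0.00014, and 0.0476 with an estimated correlation), with medians by number 957, 958 and 016 of −0.15, −0.22 and −0.24. By number the scavenger medians were 0.21, 0.37 and 0.45 and the identity medians 0.31, 0.28 and 0.37. Microglia markers summed to 1265 ± 152 CPM in Full Tumor and 1094 ± 33.9 in Myelin Alone (SD, n = 3). Over all genes edgeR called 0 members of these 3 lists with group only, and with the block 1 receptor and 2 identity genes. Adjusted over the list alone it called 0 with group only, and with the block 7 receptors, 8 identity genes and 6 NRF2 genes.

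Interferon transcripts were higher in 30 of 30 members, with a median of 2.14 (camera adjusted p = 1.6e-45, and 0.0707 with an estimated correlation) and medians by number of 2.90, 2.28 and 0.24. Ifit2 and Irf7 stood at 3.84 ± 0.78 and 3.24 ± 0.89 with the block (edgeR adjusted p = 0.113 and 0.282). EdgeR called 0 over all genes, and 24 adjusted over the list alone with group only against 27 with the block. Lists of alternative activation (0.29, camera adjusted p = 0.0015), inflammatory cytokines (0.51, 0.0020), angiogenesis and matrix (0.24, 0.0032), monocyte (0.30, 0.0032) and microglia markers (0.89, 0.0012) rose and ribosomal proteins (−0.10, 0.025) fell. Medians by number 957, 958 and 016 were 0.60, 0.81 and 0.01 for inflammatory cytokines and 1.63, 1.74 and 0.05 for monocyte markers. Ribosomal proteins were higher in 35 of 35 members in 957 (0.30) and lower in 958 and 016 (−0.24 and −0.36). With an estimated correlation adjusted p was 0.0707 to 0.873 for these 6, and 0.0329 for alternative activation with the block. EdgeR called 0 of their members over all genes and 0 or 1 adjusted over the list alone. With the block LXR targets (camera adjusted p = 0.0048), stress genes (0.0038) and mitochondrially encoded transcripts (0.015) were called higher too, at 0.198 to 0.640 with an estimated correlation, the last with medians of 0.26, −0.07 and 0.44.

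With group only, edgeR called 0 genes between Full Tumor and Myelin Alone, with 402 at an unadjusted p under 0.05 and adjusted p of 0.810 to 1.00 for the named genes, while DESeq2 called 15 and limma-voom 0, and without number 016 there were 51. The block gave 14 higher and 1 lower (995 unadjusted). In place of the 15 calls there were 5, 8, 0, 8, 3, 1 and 53 without Full Tumor 957, Tumor without Myelin 957, Myelin Alone 957, Control 958, Full Tumor 958, Myelin Alone 958 and Control 016, and 0, 0 and 120 without number 957, 958 or 016. The 53 and the 120 held all 15. The 10 named calls kept their direction without any 1 library, which the naming rule favors. Of them, 10 and 9 were lost without Myelin Alone 957 or 958.

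**Figure D4:**
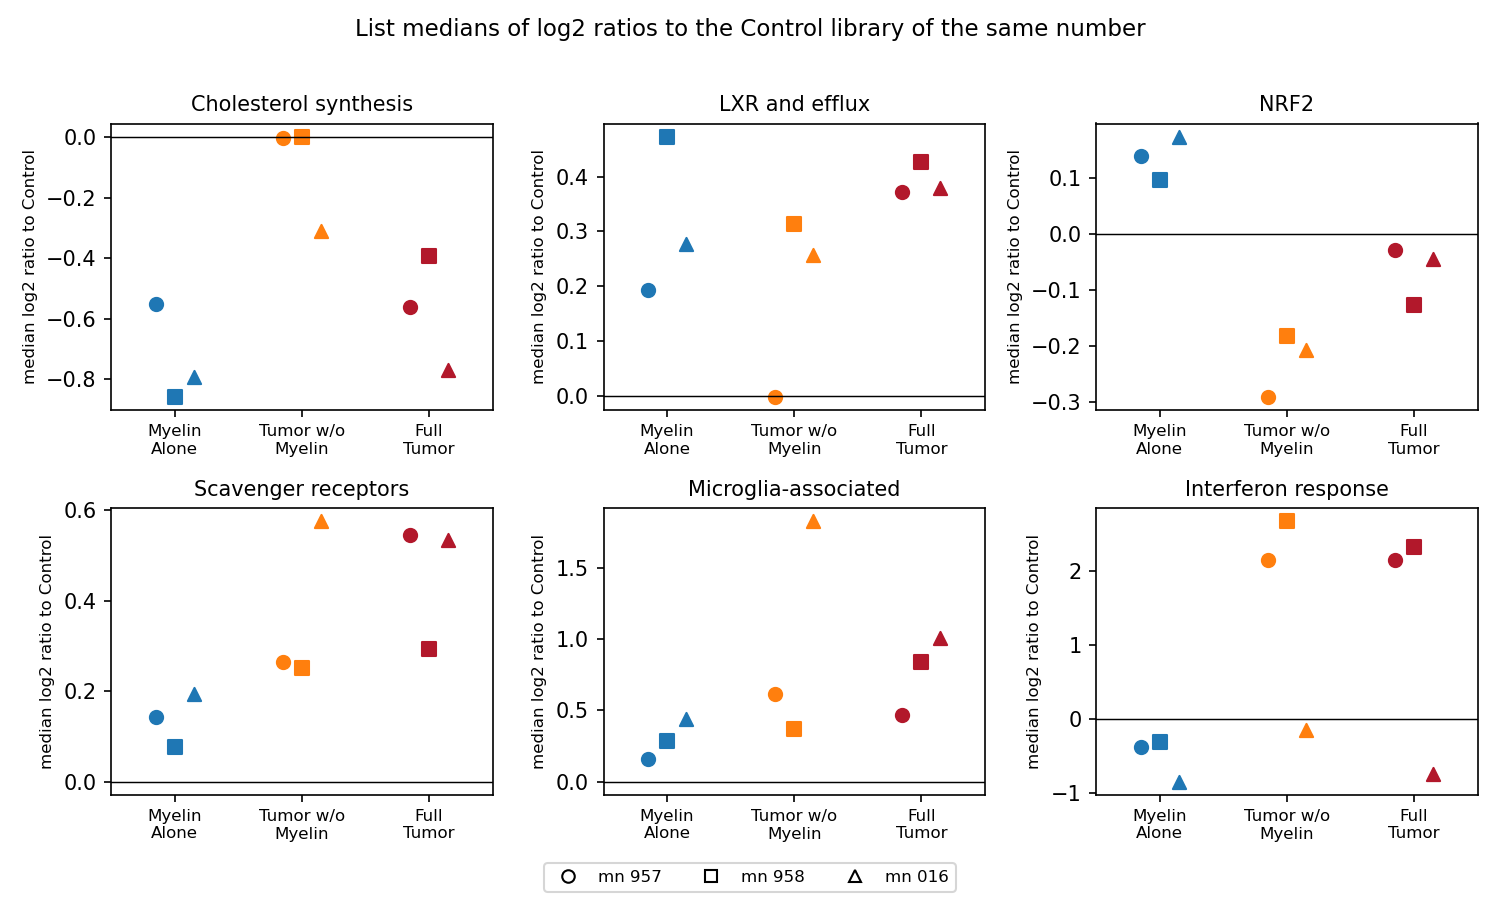
Median log2 ratio to the Control library of the same mn number for 6 gene lists, with the 3 exposed groups on the x axis and the mn number as the shape. Cholesterol synthesis medians are −0.55 to −0.86 in Myelin Alone and −0.39 to −0.77 in Full Tumor. Interferon medians in the tumor groups are 2.15 to 2.68 in numbers 957 and 958 and −0.15 and −0.74 in number 016.

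The interaction asked whether myelin had another effect in the presence of tumor material than in its absence. No gene was called by edgeR with group only or with the block (153 and 393 at an unadjusted p under 0.05, and DESeq2 0 and limma-voom 0 in both fits). The interaction was −0.04 ± 0.16 for Abcg1 and for Fcrls −1.45 ± 0.47 with the block (edgeR adjusted p of 1 for each). Of the lists, only the microglia markers passed with group only (median −0.40, camera adjusted p = 0.0223, and 0.681 with an estimated correlation). With the block LXR targets (−0.14, camera adjusted p = 0.0239), cholesterol synthesis (0.16, 0.0459) and neutrophil markers (1.17, 0.0365) passed too, with an adjusted p of 0.611 for each with an estimated correlation.

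Comparisons against Control share its 3 libraries, too few to split into sets of 2, so part of any excess agreement may come from the shared controls. With the block, Full Tumor and Tumor without Myelin correlated at r = 0.779 across genes (0.496 in simulated unchanged groups fitted the same way), with a covariance 0.0517 above the simulated one. Myelin Alone correlated with Full Tumor at 0.470 (simulated 0.497, covariance difference 0.0116) and with Tumor without Myelin at 0.284 (simulated 0.496, difference −0.00209). The last differences are small and depend on the dispersion used in the simulations, so their signs are not read as an effect. Full Tumor and Tumor without Myelin shared 46 higher and 8 lower calls, where independent lists would share 0.475 and 0.0447 and simulated unchanged groups shared 0. Neither value measures chance here, since independent lists ignore the shared Control libraries and unchanged groups hold no true changes to call. Myelin Alone shared 1 higher and 3 lower calls with Full Tumor (0.00634 and 0.00716 for independent lists), and 1 higher and 0 lower with Tumor without Myelin (0.00559 and 0.00745).

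Transcripts of other cell types were summed to show what the sorted libraries held. Microglia markers summed to 938 ± 82.5 CPM in Control, 1094 ± 33.9 in Myelin Alone, 1357 ± 229 in Tumor without Myelin and 1265 ± 152 in Full Tumor (SD, n = 3), higher than the Control of the same number in 6 of 6 tumor libraries. Oligodendrocyte transcripts, led by Gsn (1069 CPM), were higher in 5 of 6 and glioma and progenitor markers, led by Pdgfb (69.2 CPM), in 2 of 6. Astrocyte (Fabp7, 140.0 CPM), neuron (Dlg4, 6.38), endothelial (Vwf, 35.7) and T and NK cell markers (Il7r, 677) were higher in 2 of 6, and erythroid markers (Klf1, 0.236) in 3 of 6. Neutrophil (Mmp8, 103), B cell (Blnk, 238) and dendritic cell markers (Bst2, 232) were higher in 3, 5 and 6 of 6. The CPM beside each gene is its mean. Of the tested members, 4 of 7 oligodendrocyte, 1 of 6 glioma, 3 of 7 astrocyte, 0 of 4 neuron and 2 of 12 endothelial markers had 10 CPM or more in Control, as did 7 of 13 neutrophil, 3 of 4 B cell and 2 of 9 dendritic cell markers. Lists of lipid droplet (lowest camera adjusted p over the comparisons 0.321), glioma (0.458), neuron (0.178), endothelial (0.0560), T and NK cell (0.0696) and B cell markers (0.144) were called in no comparison, nor with the block.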

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

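Among the tests of this part, those of microglia transcripts, of the Control level and of exchanged libraries in number 016, those of material carried through the sort, and the counts of splits for the comparisons and the interaction were chosen only after the result was seen. Several lists stood out because the effect of myelin differed with and without tumor material by a test of that difference itself. With group only, the microglia list had an interaction of −0.40 (camera adjusted p = 0.0223, and 0.681 with an estimated correlation). With the block the interaction was −0.36 for microglia markers (camera adjusted p = 0.000549), −0.14 for LXR targets (0.0239), 0.16 for cholesterol synthesis (0.0459) and 1.17 for neutrophil markers (0.0365). Adjusted p was 0.611 for each of these 4 lists with an estimated correlation.

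Interferon transcripts moved with tumor material in numbers 957 and 958, by medians of 2.15 to 2.68, and not in number 016, where they were −0.15 and −0.74. Tumor libraries of 016 that held no tumor-exposed cells are argued against, since the microglia list of Full Tumor and Tumor without Myelin 016 stood above Control 016 by medians of 1.01 and 1.83. Myelin Alone 016 stood above Control too, by 0.44, but both tumor libraries lay above it as well, by 0.82 and 1.20 (lower quartiles 0.16 and 0.49). A high interferon level in the Control library of number 016 is argued against as the whole cause, since the 016 tumor libraries lay below the tumor libraries of the other numbers (median −2.15, quartiles −2.97 and −1.51, 29 of 30 members lower). Control 016 did lie above the other Controls, by a median of 0.61 with 19 of 30 members higher, so it may hold part of the difference. An exchange of libraries within number 016 is argued against. Over the 24 ways to name its 4 libraries, the lower interferon median of the tumor libraries reached at most 0.69 (upper quartile 1.08), under the lowest median of the other numbers, 2.15. An exchange with another number is argued against by the first principal component, on which the 4 libraries of 016 lie at 46.1 to 63.6 and the others at −53.6 to −1.87. A swap with a sample outside the 12 libraries stays open, since the lower correlation of the 016 tumor log2 ratios with those of the other numbers, 0.168 across genes, fell between the bounds of 0.1 and 0.2 set beforehand. With 1 library per group and number, what sets 016 apart, which may be biological or a batch, cannot be told apart from the number.

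Microglia-associated transcripts were higher with tumor material. Of 7 measured markers with a Control mean under 5 CPM, 5 were higher than Control in at least 5 of the 6 tumor libraries. Choosing members that are low in Control favors higher values elsewhere, and P2ry13, Tmem119 and Crybb1 were also above Control in 3 of 3 Myelin Alone libraries, so this count decides nothing. Microglia carried through the sort may explain the rise, and so may macrophages that turned these genes on. A sort on dTomato should remove cells without it, however. P2ry12 was higher in 5 of 6, Cx3cr1 in 3 and Siglech in 2. Cx3cr1 fell from 103 to 68.7 CPM in Full Tumor 957 and from 143 to 58.2 in Full Tumor 958, where Fcrls rose. It was higher in Tumor without Myelin 957 and in both tumor libraries of 016. Its level in Control could hide a small share from microglia, so these values do not decide. Whole dissociated tumor carried through the sort stays open, since the summed glioma markers were higher in 2 of 6 tumor libraries but Pdgfb, 86.5% of the Control sum, would hide a small share. Traces of tumor RNA stay open too. A set of 35 glioma, astrocyte and neuron members with a mean under 5 CPM summed higher than in Control and Myelin Alone in 4 of 6. They were chosen after 30 members with a Control mean under 1 CPM had been higher in 6 of 6 tumor libraries. Those 30 were also higher in 3 of 3 Myelin Alone libraries. Members with counts in Control 016, such as Gja1 (112) and Camk2a (79), can hide a small share in the sum. Ncan, outside these members and picked after its values were seen, had 143 and 144 counts in Full Tumor and Tumor without Myelin 016. It had 4 and 25 in those of 958, and 0 in those of 957 and in Control and Myelin Alone. It goes with traces in 016 but is only 1 gene.

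Other splits of the libraries bear on chance. With group only, 10 of 10 splits gave as many calls as the real 0 in each comparison between groups, with 0 as the highest other, and a share under 0.05 cannot be reached. With the block, the 4 splits that part all 3 pairs are also too few for a share under 0.05. As many calls came from 1 of them for Myelin Alone against Control (5, highest other 0), Full Tumor against Control (109, highest other 7), Tumor without Myelin against Control (100, highest other 0) and Full Tumor against Myelin Alone (15, highest other 0). For Full Tumor against Tumor without Myelin all 4 gave the real 0 or more, with 0 as the highest other. For the interaction 100 of 100 random groupings gave as many as the real 0, which a count of 0 makes certain, so this says nothing about chance. The highest other was 3387 calls, and what that grouping lines up with was not tested.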

How the results depend on the processing

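The comparisons with the block as the base, the pooled effects, the tumor effect by number and their alternatives were chosen only after the result was seen. Counts of calls depended on the block and on the libraries, while directions mostly held. Of the 103 gene results named, 89 kept their sign under every alternative with group only and 99 with the block. In all, 30 of 2464 alternative values changed sign with group only and 12 of 2361 with the block. Of 66 named calls with the block, 66 were kept with RLE size factors, without a low-count filter, with at least 5 CPM in 3 libraries and with DESeq2, 65 after thinning, 64 with limma-voom, 63 with library totals alone, 11 with only the groups compared, and 5, 7 and 47 without number 957, 958 or 016. All 66 kept their sign when any 1 library was left out. The first part of the naming rule asks for the same direction in the 3 same-numbered pairs. Kept signs were thus favored by the choice of genes and add little support. Of the 66, 17 kept the call as well. These were Abca1, Abcg1, Cd300lf, Cyp51, Fcrls, Il18bp, Ms4a6b, Pltp, Sqle and Tgm2 in Full Tumor against Control, and Aif1, Fcrls, Ms4a6b, Pltp, Serpinb9b, Siglec1 and Tgm2 in Tumor without Myelin against Control. Of the 57 list calls with group only, 55 were kept with library totals alone, 55 with the block, 11 with an estimated correlation, 9 with fry, and 36, 41 and 46 without number 957, 958 or 016. The pairing by mn number changed no other call than those given beside the results. The scaling moved the median log2 fold change of all genes by at most 0.058. Leaving out libraries or fitting only the groups compared leaves fewer samples, and counting only calls of at least 2-fold is stricter, by construction. For the other differences the cause was not tested. The interaction needs all 4 groups, so no fit of only the groups compared exists for it. Low counts limit what can be said of genes such as Mpo in 957 and 958, where a count of 0 allows up to 3 counts.

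With group only, where edgeR called 0 genes in each comparison, DESeq2 called 7 for Myelin Alone against Control, 43 for Full Tumor against Control, 54 for Tumor without Myelin against Control, 5 for Full Tumor against Tumor without Myelin and 15 for Full Tumor against Myelin Alone. The replicate block gave 5, 109, 100, 0 and 15 in that order. Without a low-count filter there were 3 for Full Tumor against Control and 1 for Tumor without Myelin against Control. Leaving out libraries or numbers gave 0 to 69, 0 to 61 and 0 to 51 for Full Tumor against Control, Tumor without Myelin against Control and Full Tumor against Myelin Alone, the highest of each without number 016.

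With the replicate block as the base, no low-count filter gave 20 for Myelin Alone against Control, 178 for Full Tumor against Control, 188 for Tumor without Myelin against Control, 5 for Full Tumor against Tumor without Myelin and 89 for Full Tumor against Myelin Alone. DESeq2 with the block gave 64, 343, 316, 13 and 154 in the same order. At least 5 CPM in 3 libraries gave 8, 155 and 30, and limma-voom 9, 176 and 35, for Myelin Alone against Control, Tumor without Myelin against Control and Full Tumor against Myelin Alone. With only the groups compared there were 1, 19, 6 and 1 for Myelin Alone, Full Tumor and Tumor without Myelin against Control and for Full Tumor against Myelin Alone. Calls of at least 2-fold numbered 3, 47 and 48 for the first 3 of these. Leaving out libraries or numbers gave 0 to 9, 1 to 183 and 4 to 153 for Myelin Alone, Full Tumor and Tumor without Myelin against Control, 0 to 1 for Full Tumor against Tumor without Myelin and 0 to 120 for Full Tumor against Myelin Alone. The correlation of the myelin effects was 0.133 to 0.204 without a number, lowest without 958 and highest without 016.

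For the pooled myelin effect (21 calls) DESeq2 gave 129, counting only calls of at least 2-fold gave 6, and leave-outs gave 0 to 26. For the pooled tumor effect (330 calls) these were 673, 96 and 56 to 385. Without number 016 the pooled myelin effect gave 15 higher and 11 lower, which held 13 of the 21, and the pooled tumor effect 237 and 44, which held 193 of the 330. DESeq2 gave 60 higher and 69 lower for myelin. For the tumor effect of 016 minus the others (94 calls) no low-count filter gave 205, at least 5 CPM 165, DESeq2 343, limma-voom 144 and leave-outs 25 to 118.

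Sign changes were found in genes with small or scattered log2 fold changes. EdgeR called no gene with group only, but with the block Ccl2 and Mpo in Full Tumor and Mpo and Lat in Tumor without Myelin were called against Control, and their directions with group only rest on the libraries of 016. When libraries or numbers were left out, the interaction for Abcg1 was −0.23 to 0.16 with group only and −0.15 to 0.091 with the block. For Myelin Alone against Control such ranges were −0.20 to 0.83 for Apoe (lowest without Myelin Alone 958), −0.044 to 0.26 for Gpnmb (lowest without Control 958), −0.22 to 0.64 for Spp1 (lowest without Myelin Alone 016) and −0.19 to 0.045 for Trem2 (highest without Control 958). With the block Trem2 ranged from −0.13 to 0.0087, the last without Myelin Alone 957. The range was −2.14 to 6.13 for Ccl2, Full Tumor vs Control, and −12.43 to 1.09 for Mpo, Full Tumor vs Control, in both the lower end without Full Tumor 016 and the higher without Control 016. In this comparison it was −3.0e-04 to 0.30 for Gpnmb, −0.24 to 0.049 for Trem2, −0.011 to 0.89 for Spp1 and −1.19 to 0.32 for Mki67 (−0.80 to 0.11 with the block). Gpnmb was lowest without Control 958, Spp1 lowest and Trem2 highest without Full Tumor 016, and Mki67 highest without number 958. Arg1 ranged from −1.01 without number 016 to 4.37 without 958 with the block. The range was −12.47 to 2.52 for Mpo, Tumor without Myelin vs Control, and −3.37 to 0.46 for Lat, Tumor without Myelin vs Control, both above 0 without Control 016. For Full Tumor against Myelin Alone it was −0.030 to 0.29 for Abcg1, lowest without Myelin Alone 016. The median of ribosomal proteins there was −0.27 to 1.7e-04, the last without number 016.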

Other observations

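The pooled effects, the tumor effect by number and the counts of myelin and tumor transcripts were chosen only after the result was seen, and the exchange tests of the pooled effects before. The myelin effect, averaged over its presence without and with tumor material and fitted with the block, reached further genes. Gsta3, a glutathione transferase (ENSMUSG00000025934, chromosome 1, 21240589 to 21265661), was higher with myelin, at 31.8 ± 11.8 CPM in Control and 65.6 ± 7.48 in Myelin Alone, and 19.0 ± 5.65 in Tumor without Myelin and 41.0 ± 5.27 in Full Tumor (SD, n = 3). It rose by 1.13 ± 0.13 on the log2 scale (edgeR adjusted p = 0.00326). Stra6l, a membrane receptor for retinol-binding protein, rose by 0.70 ± 0.12 and the membrane-bound glutathione transferase Mgst1 by 0.37 ± 0.06 (edgeR adjusted p = 0.0463 and 0.0272). Insig1, which holds SREBP in the endoplasmic reticulum when sterol is ample, fell by 0.92 ± 0.13 and the paired receptor gene Pilra by 1.16 ± 0.18 (edgeR adjusted p = 0.0220 and 0.0344). The NRF2 list rose with myelin (median 0.17, camera adjusted p = 8.6e-06, and 0.019 with an estimated correlation) and fell with tumor material (−0.23, 8.5e-10 and 0.0031). These genes were chosen after their values were seen.

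For the tumor effect by mn number, camera at the preset correlation called lists beyond interferon. The fit takes both tumor libraries of a number as replicates, and its Control and Myelin Alone likewise, after a shared myelin effect. The camera and edgeR p-values of this contrast thus measure the spread within numbers. They cannot show that 016 differs from the other numbers by more than numbers differ among themselves. In 016 minus the mean of the other numbers, the interferon list was lower by a median of −2.59, which restates the pattern that led to this contrast and adds no support to it. Proliferation genes were higher by a median of 1.11 (camera adjusted p = 2.1e-32), and hypoxia genes by 0.27 (1.3e-05), and inflammatory cytokines were lower with a median of −1.01 (3.8e-05). Adjusted p was 0.0593 for each of these 3 lists with an estimated correlation. Markers of other cell types moved as well, with neutrophil (−2.35, camera adjusted p = 0.0066), monocyte (−1.48, 0.0040) and dendritic cell markers (−1.27, 0.0040) lower. Mitochondrially encoded transcripts (0.51, 0.00049) and scavenger receptors (0.27, 0.039) were higher, and ribosomal proteins (−0.16, 0.0049), class II presentation (−0.10, 0.0040), stress genes (−0.26, 0.0040) and cholesterol synthesis (−0.24, 0.0091) lower. These 9 lists had an adjusted p of 0.202 to 0.630 with an estimated correlation, and whether cell make-up or RNA quality sets 016 apart was not tested. With tumor material the proliferation medians by number 957, 958 and 016 were −0.24, −0.74 and 0.91 without myelin and −0.37, −0.75 and 0.42 with it. EdgeR called 24 genes higher and 70 lower for this contrast (1444 unadjusted), 20 of the lower ones from the interferon list. The balance depended on the setting. RLE size factors gave 23 higher and 69 lower, DESeq2 173 and 170, and no low-count filter 88 and 117. Without Tumor without Myelin 016 there were 0 higher and 34 lower. The 94 calls became 58, 44, 25 and 34 without Full Tumor 957 or Control, Full Tumor or Tumor without Myelin 016, and 37 and 33 without number 957 or 958.

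The pooled myelin effect gave 7 higher and 14 lower genes by edgeR with the block (983 unadjusted) and the pooled tumor effect 228 and 102 (1766 unadjusted). Exchanging labels within same-numbered pairs gave as many calls in 1 of 32 exchanges for each, the real one. The highest other counts were 0 and 9. The share lies under 0.05, but it takes the pairs of a number as independent of each other. Exchanges of whole mn numbers are too few for such a share. The pooled effects were also chosen after the results were seen, so chance is not excluded. The 21 myelin calls became 6 without Control 957, Full Tumor 957 or Tumor without Myelin 957, 7, 8, 10 and 5 without Myelin Alone 957, Control 958, Full Tumor 958 and Myelin Alone 958, 12 and 11 without Full Tumor or Myelin Alone 016, and 0 and 3 without number 957 or 958. Without 016 the balance turned to 15 higher and 11 lower, which held 13 of the 21. The 330 tumor calls became 178, 155, 198, 209, 191 and 188 without Control 957, Tumor without Myelin 957, Control 958, Full Tumor 958, Tumor without Myelin 958 and Myelin Alone 958, and 85 and 56 without number 957 or 958.

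A few transcripts of brain cells were seen in some libraries and not in others. Mobp, an oligodendrocyte gene of the myelin sheath (ENSMUSG00000032517, chromosome 9, 120149707 to 120181484), had 10, 8 and 8 counts in Myelin Alone and 16, 16 and 13 in Full Tumor, and 0 in each Control and Tumor without Myelin library, which allows up to 3 counts in each. It was chosen for this pattern after its values were seen, so no test of it would count. With any count taken as on, such an on and off pattern was seen for 2 genes at this split. The mean was 1.53 and the highest 10 over the 462 splits of the 12 libraries into 6 and 6. With at least 8 counts taken as on, as in Mobp, 12 genes showed it over all 462 splits together. Mobp was picked for its split, so chance is not excluded. The myelin gene Mbp did not follow this pattern, with 6665 counts in the myelin libraries and 6563 in the others. Its 973 to 1402 counts in the Control libraries would hide a few counts from myelin. Ncan, a proteoglycan gene of brain matrix (ENSMUSG00000002341, on chromosome 8), also chosen after its values were seen, had 0 counts in Control, Myelin Alone and both tumor libraries of 957. It had 4 and 25 counts in Full Tumor and Tumor without Myelin 958 and 143 and 144 in those of 016.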
